A study of Mus musculus with 2 samples.

How the data were processed

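Total RNA of dissected mouse ureters (NMRI strain) at E14.5 was measured on 2 two-colour Agilent arrays, each with a knockout and a control sample, from 150 ng of input RNA per the labels. How many embryos each sample holds, and whether the arrays come from separate litters, is not given in the sources used here. The p-values of single genes therefore rest on the spread between these arrays, moderated by a variance prior pooled over genes. Those of gene lists at a preset correlation set the genes of a list against other genes and do not measure the spread between arrays. Both arrays lay on a single slide and were scanned together, so slide and scan were the same for all values. Sex and dye orientation changed together between the arrays and cannot be separated.

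Spot intensity was read by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes, as the mean signal and the median local background of each channel. The deposited files also hold processed intensity, which the scanner software background-subtracted, detrended and dye-normalised, and a log10 ratio of red over green per the file headers. The authors' deposited table is a score, a signed fold with 1 value for each of 39429 probes. Its median is 1 on each array, and 11261 probes on replicate 1 and 11489 on replicate 2 stand at exactly 1. Set against the processed signals, its signed log2 correlated with red over green at 0.822 on replicate 1 and -0.739 on replicate 2. By the dyes in the labels that is control over knockout on both arrays, whereas its titles name the knockout first. How the score was scaled, centred and floored is not given in the sources used here. It entered only as an alternative, with its columns turned to knockout over control.

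Values computed here started from the mean signals. Background was corrected by normexp with an offset of 50, arrays were normalised by loess with control spots at weight 0, and control spots and outlier-marked spots (3.52% of probe spots on replicate 1 and 3.66% on replicate 2) were left out. No spot was saturated. The 4 spots of a probe were averaged; their SD was 0.0575 and 0.0600 (median, log2) on the 2 arrays. The sign of replicate 1 was turned so that positive means higher in labelled knockout. A probe was kept if at least 2 of its spots were well above background on both arrays in the channels of at least 1 genotype, which left 26522 of 39429 probes. A gene was its brightest probe. Of the 66 genes that passed, 10 had another kept probe, and all 11 such probes went the same way. Where one genotype was not well above background on any array only a lower bound would hold, which applied to none of the named genes.

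Probe names came from the array files and were updated through a RefSeq table (GRCm38.p6, names only). There, 28328 probes matched by accession, 3400 by symbol and 243 by an older symbol, and 7458 kept the file's name. Coordinates are those of the array design on mm9. Exons and untranslated regions of that build were not used here.

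The test was limma 3.58.1 (R 4.3.3) on the 2 log2 ratios against 0, two-sided, with Benjamini-Hochberg adjustment over 20104 genes. With 1 residual degree of freedom per gene, the moderated variance rests mainly on a prior of 9.21 degrees of freedom. A rule of size, at least 1.5-fold in one direction on each array, was counted beside it with no test. Gene lists (32, of which 7 primary) were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with at least 3 measured members. The genes named, by a rule fixed then too, are the 12 per direction with the largest mean log2 ratio among genes with a symbol that passed the test and were at least 1.5-fold apart in one direction on each array. Smad4, the sex check genes and, per list, up to 4 members with the largest absolute mean plus those that passed are named too. One such member of the general epithelium list is not reported here. Names of predicted, clone-based or unlocated transcripts were left out.

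The steps were tested on simulated data with 2 arrays and 20104 genes. Of planted changes, 23 of 67 at 1.5-fold, 56 of 67 at 2-fold and 66 of 66 at 3-fold passed in the planted direction. There, 11 unchanged genes were called. Noise was drawn independently for each gene from the fitted prior, as the test assumes, with no dye effect of single genes. Power and error in the real arrays may therefore be worse. Alternatives were Agilent's processed signals, no background correction, an offset of 0, median centring, Aquantile between arrays, no filter or a stricter filter, the mean over probes, the authors' deposited values, a prior with trend, a 2-fold threshold, other list tests, each array alone, and 4 unpaired channels. Plots were drawn with matplotlib 3.10.9.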

Results

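The arrays compared gene expression in mouse ureters at E14.5 between embryos labelled Pax2-cre/+;Smad4(fl/fl), a knockout in the ureteric epithelium, and controls labelled Smad4(fl/?). SMAD4 is the shared partner of the receptor-activated SMAD proteins in BMP and TGF-beta signalling. The comparison asks which transcripts are deregulated in ureters whose epithelium lacks Smad4. There were 2 arrays, and on each a knockout sample and a control sample were hybridised together in different dyes. Replicate 1 was labelled female with the knockout in Cy3, and replicate 2 was labelled male with the knockout in Cy5. On replicate 1, 69.1% of probes were well above background in the knockout channel and 67.6% in the control channel. The shares on replicate 2 were 66.5% and 68.6%. The number of arrays, 2, limits the precision of every value.

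Smad4 itself was 1.26-fold lower in the channels labelled knockout, with a log2 ratio of knockout over control of -0.33 ± 0.36 (SD, n = 2 arrays), and did not pass the test (limma adjusted p = 1.00). Its brighter probe, at mm9 chromosome 18 positions 73798670 to 73798729, read -0.58 on replicate 1 and -0.08 on replicate 2. The second probe, at 73799668 to 73799727, read -0.09 and -0.33. Whether either probe lies within the floxed part was not determined here, so Smad4 does not check the labels. Directions throughout follow the dyes given in the labels, and a channel is called labelled knockout or labelled control. The authors' deposited table, if read in the order of its titles as knockout over control, runs the opposite way on both arrays. In that table the signed fold of Upk3a is -2.72 on replicate 1 and -3.31 on replicate 2, and that of Prm1 is 4.75 and 4.83. Turning every sign would exchange the sets of genes below and leave the sizes and tests as they are.

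Upk3a, Upk1a and Upk1b encode uroplakins, membrane proteins of the urothelial surface. Upk3a was 2.94-fold higher in labelled knockout (log2 1.55 ± 0.18, SD, n = 2, adjusted p = 0.000882), Upk1a 2.57-fold (1.36 ± 0.23) and Upk1b 2.47-fold (1.31 ± 0.13). Prm1, a protamine that packs sperm DNA, had the largest fold in the other direction, 4.63-fold higher in labelled control (log2 -2.21 ± 0.03, adjusted p = 6.82e-05). Clu, which encodes the secreted chaperone clusterin, was 3.04-fold higher in labelled control (log2 -1.61 ± 0.20), Cited4, a transcriptional co-activator, 2.83-fold (-1.50 ± 0.00345) and Aldh1a3, an enzyme of retinoic acid synthesis, 2.46-fold (-1.30 ± 0.03). Of 20104 genes tested, 66 passed an adjusted p of 0.05 in limma, 46 of them higher in labelled knockout and 20 higher in labelled control. Each of the 66 had the same sign on both arrays, which a pass with 2 arrays nearly requires.

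Further genes with large values in labelled knockout were Ldoc1 (2.71-fold), the annexin gene Anxa8 (2.63-fold), the gasdermin gene Gsdmc3 (2.53-fold), Perp, a component of desmosomes (2.52-fold), and the scaffold protein gene Pdzk1 (2.51-fold). Afp, which encodes alpha-fetoprotein, was 2.49-fold higher, the serpin gene Serpinb5 2.24-fold, S100a14 2.22-fold and the aldehyde dehydrogenase gene Aldh3b2 2.20-fold. In the other direction, Slc16a5 of the monocarboxylate transporter family was 2.27-fold higher in labelled control and Guca2a, which encodes guanylin, 2.27-fold. The chemokine gene Cxcl13 was 2.18-fold higher, Tesc 2.14-fold, the ammonium transporter gene Rhcg 2.11-fold, the cadherin gene Cdh22 2.09-fold and the metalloprotease gene Adamts16 1.91-fold. These and Nkx6-3 passed the test, with adjusted p from 0.00126 for Anxa8 to 0.0494 for Cxcl13, and their SD in log2 (n = 2) ran from 0.02 for Pdzk1 to 0.69 for Cxcl13. With unpaired channels Afp (adjusted p = 0.993), Cxcl13 (0.416), Serpinb5 (0.0893), Rhcg (0.0620) and Aldh3b2 (0.0531) did not pass, and with the prior with trend Serpinb5 (0.0613) and Cxcl13 (0.140) did not. The homeobox gene Nkx6-3 was higher in labelled control too, but was well above background in labelled knockout on 1 of the 2 arrays, so its fold is uncertain. Its log2 ratio was -1.12 here, -1.67 with an offset of 0, -2.57 with Agilent's processed signals and -2.50 with the authors' deposited values, beyond that of Prm1 there (-2.27 and -2.26). Cxcl13 read -0.64 on replicate 1 and -1.61 on replicate 2, and Serpinb5 0.77 on replicate 1 and 1.55 on replicate 2, with a mean of 1.82 with processed signals.

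By size alone, 74 genes were at least 1.5-fold apart in one direction on each array, 53 higher in labelled knockout and 21 in labelled control. Another 23 genes were that far apart in opposite directions, and 22 of these were brighter in Cy5 on both arrays. With median centring these were 322 genes, 321 of them brighter in Cy5, and with processed signals 43, of which 39 were. The log2 ratios of all genes hardly correlated between the arrays (Pearson r = 0.0168, Spearman rho = -0.0820, across genes, which are not independent replicates). In limma, 914 of the 20104 genes had an unadjusted p under 0.05, no more than that threshold would give without any change. The count of 66 became 0 when loess was replaced by median centring and 0 with dim probes kept, at 347 and 1097 genes with an unadjusted p under 0.05 and with 76 and 74 genes at least 1.5-fold apart in one direction. With the 4 channels as unpaired samples it was 29, and with Agilent's processed signals 194.

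**Figure D1:**
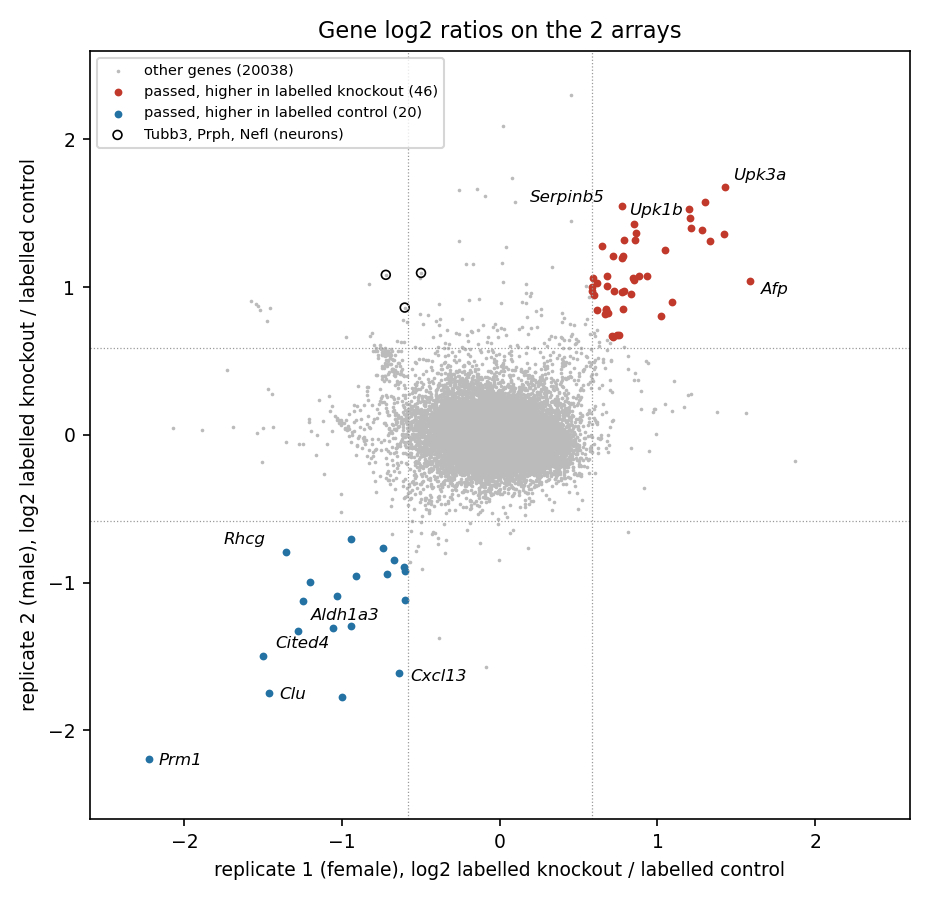
Each point is a gene, with its log2 ratio of labelled knockout over labelled control on replicate 1 (x axis) and on replicate 2 (y axis); dotted lines mark 1.5-fold. The 46 genes that passed in labelled knockout lie at the upper right and the 20 in labelled control at the lower left, with Prm1 at -2.23 and -2.19, while the neuronal genes Tubb3, Prph and Nefl (open circles) lie at the upper left.

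Of 17 measured genes of urothelial differentiation, 7 passed the test, all of them higher in labelled knockout, and 10 did not pass. Adjusted over the list alone, 11 were higher in labelled knockout. Besides Upk3a, Upk1a and Upk1b, those that passed over all genes were Grhl3, a transcription factor of the differentiating surface layer (2.13-fold), Upk3bl (1.84-fold), Upk3b (1.71-fold) and Pparg, a nuclear receptor (1.61-fold). Upk2, another uroplakin, read 0.45 on replicate 1 and 1.45 on replicate 2 and did not pass (adjusted p = 0.136), and is named after its value was seen. The list mean was log2 0.60 (camera adjusted p = 1.92e-24, and adjusted p = 0.669 with an estimated correlation). The median was 0.45 on replicate 1 and 0.62 on replicate 2. With the 4 channels as unpaired samples Grhl3 (adjusted p = 0.215), Upk3bl (0.0531), Upk3b (0.0818) and Pparg (0.0659) did not pass, and Upk3b read 1.57 with processed signals.

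General epithelial genes were also higher in labelled knockout as a list, with a mean of log2 0.19 over 20 genes (camera adjusted p = 1.85e-08, and adjusted p = 0.669 with an estimated correlation). On both arrays 18 of the 20 were above 0. None of the 20 passed the test singly, and adjusted over the list alone 2 were higher in labelled knockout. Krt19, a simple-epithelium keratin, read log2 0.53 ± 0.05 (SD, n = 2) and Ap1m2 0.32 ± 0.13, while the claudin gene Cldn3 read -0.37 ± 0.03. Of 14 basal epithelial genes none passed, and the list did not either (mean 0.08, camera adjusted p = 0.135). Adjusted over the list alone, 2 were higher in labelled knockout and 2 in labelled control. The laminin chain genes Lama3 and Lamb3 read 0.61 ± 0.14 and 0.45 ± 0.07, and Krt6a and the hyaluronan receptor gene Cd44 read -0.41 ± 0.12 and -0.35 ± 0.03. The 7 measured genes of squamous keratinocytes had a mean of 0.17 (camera adjusted p = 0.00978, and adjusted p = 0.669 with an estimated correlation). None passed over all genes and 2 were higher in labelled knockout adjusted over the list alone, with Ivl at 0.49 ± 0.06 and Lypd3 at 0.48 ± 0.35. Lama3 passed in 5 alternative settings and Ivl in 4, where Ivl read up to 0.88.

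**Figure D2:**
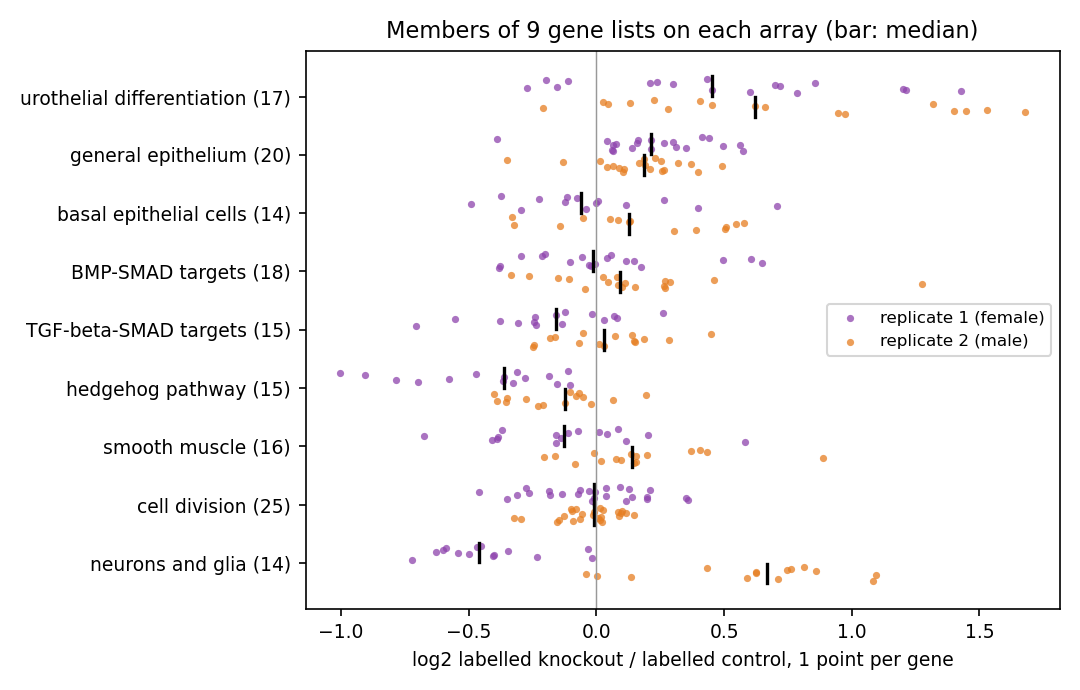
Each point is a gene of one of 9 lists, with its log2 ratio of labelled knockout over labelled control on the x axis, in purple for replicate 1 and orange for replicate 2; black bars are medians and the number of measured genes is in brackets. The urothelial medians are 0.45 and 0.62, and those of neurons and glia are -0.46 and 0.67.

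Among 18 targets of BMP-SMAD signalling, Msx2, a homeobox gene, passed at 1.95-fold higher in labelled knockout (log2 0.96 ± 0.44, adjusted p = 0.0359, and 0.143 with unpaired channels), and 17 did not pass. Adjusted over the list alone, 2 were higher in labelled knockout. Id1 and Id2, inhibitors of basic helix-loop-helix factors, read 0.53 ± 0.10 and 0.38 ± 0.16, and Atoh8 read -0.27 ± 0.09. The list did not pass (mean 0.09, camera adjusted p = 0.105), with a mean of 0.0334 on replicate 1 alone and 0.14 on replicate 2 alone. None of 15 TGF-beta-SMAD targets passed, singly, adjusted over the list alone or as a list (mean -0.07, camera adjusted p = 0.1704). Thbs1, which encodes thrombospondin, read -0.48 ± 0.32, the cell cycle inhibitor gene Cdkn1a 0.36 ± 0.13, Pmepa1 -0.21 ± 0.04 and Tgfbi -0.19 ± 0.08. The 26 ligands, receptors and antagonists of these pathways were higher in labelled control as a list (mean -0.11, camera adjusted p = 0.00126, and adjusted p = 0.669 with an estimated correlation). None of them passed singly or adjusted over the list alone, with a list mean of -0.15 on replicate 1 alone and -0.0727 on replicate 2 alone, and with Inhbb at -0.34 ± 0.31, Bmp4 at -0.29 ± 0.15 and Tgfb3 at -0.28 ± 0.09. The 8 SMAD genes did not pass as a list (mean -0.08, camera adjusted p = 0.242), with Smad3 at -0.18 ± 0.15.

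The hedgehog pathway was higher in labelled control as a list, with a mean of log2 -0.30 over 15 genes (camera adjusted p = 2.50e-10, and adjusted p = 0.669 with an estimated correlation). On both arrays 13 of the 15 were below 0, and the list mean was -0.44 on replicate 1 alone and -0.16 on replicate 2 alone. The lists of ureteric mesenchyme (mean -0.13) and fibroblast matrix (-0.14) lay in the same direction, and general epithelium (0.19) in the other. None of the 15 hedgehog genes passed over all genes. Adjusted over the list alone 4 were higher in labelled control, among them Foxf1 and Hhip but not Foxl1 or Ptch1. Foxf1 and Foxl1, forkhead genes that respond to hedgehog signals in mesenchyme, read -0.70 ± 0.43 and -0.49 ± 0.58. Hhip, which encodes a hedgehog-binding protein, read -0.59 ± 0.28 and the receptor gene Ptch1 -0.41 ± 0.41. Foxf1 passed in 3 alternative settings and read -0.45 with the mean over probes. The retinoic acid pathway was likewise higher in labelled control as a list of 14 genes (mean -0.17, camera adjusted p = 0.00888, and adjusted p = 0.669 with an estimated correlation). Its median was -0.11, with 7 of the 14 below 0 and 1 above 0 on both arrays, and Aldh1a3 at -1.30 weighed most in the mean. Aldh1a3 passed and 13 did not, and adjusted over the list alone 1 was higher in each direction, with Aldh1a1 at 0.45 ± 0.16. The list mean was -0.25 on replicate 1 alone and -0.0836 on replicate 2 alone. The FGF list had a mean of -0.13 (camera adjusted p = 0.00719, and adjusted p = 0.726 with an estimated correlation), from -0.25 on replicate 1 alone and -0.00528 on replicate 2 alone, with Fgf9 at -0.31 ± 0.37 and Fgfr3 at 0.27 ± 0.03. The NOTCH list had a mean of -0.10 (camera adjusted p = 0.0255, and adjusted p = 0.669 with an estimated correlation), with Notch1 at -0.41 ± 0.12 and Jag2 at 0.30 ± 0.10. No member of the FGF or NOTCH list passed, singly or adjusted over the list alone. Canonical WNT targets did not pass (mean -0.07, camera adjusted p = 0.156).

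Smooth muscle genes did not pass as a list (16 genes, mean 0.02, camera adjusted p = 0.539), and none passed singly or adjusted over the list alone. Myocd, the co-activator that drives smooth muscle genes, read -0.44 ± 0.33, Tnnt2 0.36 ± 0.31, Pcp4 0.25 ± 0.90 and Acta2 0.24 ± 0.23. Cell division genes did not pass either (25 genes, mean -0.03, camera adjusted p = 0.575), with Mcm3 at -0.22 ± 0.13 and Aurkb at -0.19 ± 0.12. Ureteric mesenchyme was higher in labelled control (mean -0.13, camera adjusted p = 0.0123, and adjusted p = 0.726 with an estimated correlation). None of its 14 genes passed, and adjusted over the list alone 1 was higher in each direction, with a list mean of -0.23 on replicate 1 alone and -0.0328 on replicate 2 alone, and with Foxf1, which the hedgehog list also holds, at -0.70 ± 0.43, Pdgfrb at -0.32 ± 0.33, Sox9 at -0.32 ± 0.29 and Car3 at 0.52 ± 0.08. Fibroblast matrix genes were higher in labelled control too (mean -0.14, camera adjusted p = 0.00978, and adjusted p = 0.669 with an estimated correlation). None of the 15 passed and 1 was higher in labelled control adjusted over the list alone, with a list mean of -0.21 on replicate 1 alone and -0.0626 on replicate 2 alone, and with Col1a1 at -0.48 ± 0.19 and Col1a2 at -0.41 ± 0.72.

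Of 12 collecting duct genes, 3 passed, each higher in labelled knockout, and 9 did not. These were the water channel gene Aqp3 (1.97-fold), Foxi1, a forkhead gene of intercalated cells (1.76-fold), and Elf5 (1.70-fold). The sodium channel gene Scnn1a read log2 -0.68 ± 0.01 without passing (adjusted p = 0.0546), and passed in 7 alternative settings. With unpaired channels Aqp3 (adjusted p = 0.0578), Foxi1 (0.0636) and Elf5 (0.0582) did not pass. Adjusted over the list alone, 3 were higher in labelled knockout and 2 in labelled control. The list was higher in labelled knockout (mean 0.18, camera adjusted p = 0.00468, and adjusted p = 0.669 with an estimated correlation).

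Skeletal muscle markers were higher in labelled knockout as a list (mean 0.29, camera adjusted p = 2.22e-05, and adjusted p = 0.669 with an estimated correlation), with a mean of 0.46 on replicate 1 alone and 0.12 on replicate 2 alone. None of the 11 passed over all genes and 5 were higher in labelled knockout adjusted over the list alone. Myh8, a myosin of developing muscle, read 1.56 on replicate 1 and 0.15 on replicate 2, Tnnc2 0.97 on replicate 1 and 0.15 on replicate 2, and Myl1 0.59 on replicate 1 and 0.41 on replicate 2. The list of 7 mesothelial genes had a mean of log2 0.21 (camera adjusted p = 0.00468, and adjusted p = 0.669 with an estimated correlation). Upk3b passed and 6 did not, and 3 were higher in labelled knockout adjusted over the list alone. The members with the largest means, Upk3b and Krt19, are also in the urothelial and general epithelium lists, and of the others Msln read 0.41 ± 0.14, Gpm6a 0.13 ± 0.15, Nkain4 -0.03 ± 0.19, Lrrn4 -0.13 ± 0.07 and Wt1 -0.18 ± 0.44. The 14 macrophage genes had a mean of 0.11 (camera adjusted p = 0.00845, and adjusted p = 0.669 with an estimated correlation), and none passed, with Lyz2 at 0.39 ± 0.30. The 13 endothelial genes were higher in labelled control as a list (mean -0.12, camera adjusted p = 0.00978, and adjusted p = 0.734 with an estimated correlation). None of these genes passed, with Flt1 at -0.37 ± 0.09 and Cdh5 at -0.36 ± 0.25. Their mean was -0.0163 on replicate 1 alone and -0.22 on replicate 2 alone.

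Neuron and glia genes did not pass as a list (mean 0.09, camera adjusted p = 0.242) and had opposite medians, log2 -0.46 on replicate 1 and 0.67 on replicate 2. The nephric duct and ureteric bud tip list (mean -0.01, camera adjusted p = 0.901) and p53 targets and cell cycle inhibitors (mean 0.07, camera adjusted p = 0.0848) did not pass, the latter with a mean of 0.0227 on replicate 1 alone and 0.12 on replicate 2 alone. Red blood cells (mean 0.05, camera adjusted p = 0.175), gonad and adrenal (mean 0.03, camera adjusted p = 0.539) and interferon response genes (mean 0.07, camera adjusted p = 0.175) did not pass. Hypoxia and glycolysis genes (mean -0.01, camera adjusted p = 0.901) and the sex-linked genes (mean 0.11, camera adjusted p = 0.135, and 0.0415 with dim probes kept) did not pass. Nephron and nephron progenitor genes (mean 0.06, median -0.04, camera adjusted p = 0.279) and immediate early and heat shock genes (mean 0.00781, median -0.02, camera adjusted p = 0.901) did not pass, and in both the mean and the median differ in sign. In all, camera with a preset correlation passed 15 of 32 lists, 7 higher in labelled knockout and 8 in labelled control. None passed with an estimated correlation (smallest adjusted p = 0.669, with 0 lists at an unadjusted p under 0.05) or with fry (smallest adjusted p = 0.554, also 0 lists), both with 1 residual degree of freedom.

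The sex labels were checked with Xist, the transcript that coats the inactive X chromosome, and with Y-linked genes. Xist had a normalised signal of 4103 in labelled knockout and 4369 in labelled control on the female array, against 333 and 988 on the male array. Ddx3y had signals of 5486 and 4749 on the male array, against 527 and 255 on the female array. Eif2s3y had signals of 4729 and 4185 on the male array, against 492 and 264 on the female array. The arrays thus differed in the direction their labels give, and on each array the channels were unequal for transcripts of the other sex. In log2, Xist read -0.09 on replicate 1 and -1.57 on replicate 2, and Ddx3y read 1.05 on replicate 1 and 0.21 on replicate 2. Uty was well above background on the male array alone, and Kdm5d on neither array.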

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

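The tests of a second neural list, of a sex-dependent effect, of a constant probe signal and of mixed-sex pools were chosen only after the result was seen, and the genes Tubb3, Nefl and Rn18s were chosen after their values were seen.

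Neuron and glia genes went opposite ways on the arrays, with a median log2 ratio of labelled knockout over labelled control of -0.46 on replicate 1 (female) and 0.67 on replicate 2 (male), a difference that was not tested, and Tubb3, a neuronal tubulin gene, read -0.72 on replicate 1 and 1.08 on replicate 2, Prph -0.50 on replicate 1 and 1.10 on replicate 2 and Nefl -0.60 on replicate 1 and 0.86 on replicate 2. A dye effect tied to the base composition of the probes is argued against. The list's median Cy5 excess of 0.468 exceeded the upper bound of 0.0991 for random lists matched on probe GC content and intensity. That test does not reach a dye bias of another kind, which was not tested. Such a bias would also make genes brighter in Cy5 on both arrays. A candidate explanation is more neural tissue in the sample that carried Cy5 on each array, since 18 of 25 measured genes of a second neural list were brighter in Cy5 on both arrays, against 27.1% of all genes, and 17 of 24 without Ina, whose value may have been seen when the list was written, so the list is not independent evidence. A genotype effect that differs between the sexes cannot be told apart from this, because sex and dye orientation changed together, and 22 of the 23 genes at least 1.5-fold apart in opposite directions were brighter in Cy5 (321 of 322 with median centring and 38 of 43 with the authors' deposited values). These 23 also hold genes that the neural explanation does not cover, with Rn18s, a ribosomal RNA gene, at -0.97 on replicate 1 and 0.66 on replicate 2 and 6 transcripts without a symbol at -1.58 to -1.45 on replicate 1.

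Transcripts of the other sex gave a signal on both arrays: Ddx3y had 527 and Eif2s3y 492 in the labelled-knockout channel of the female array, and Xist had 988 in the labelled-control channel of the male array. Against the mean of the other array these are 10.3%, 11.03% and 23.3%, and the partner channels had 4.98%, 5.93% and 7.85%. A constant signal of the probes without the transcript, equal in both dyes, would not give the difference of Ddx3y on the female array. That was log2 1.05, beyond 1.5-fold, but this value prompted the test and is not independent evidence. For Ddx3y, Eif2s3y and Xist alike, the brighter of the channels was the one in Cy3. A residual probe signal that is stronger in Cy3 is therefore not excluded and was not tested. RNA from embryos of the other sex in part of the samples is a possible explanation that stays open, since the 2 of 2 Y-linked genes above background on the female array, over 1.5-fold higher in its labelled-knockout channel, are the observation itself and not independent evidence. No biological explanation was tested.

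Canonical WNT targets had opposite medians, -0.24 on replicate 1 and 0.10 on replicate 2, with Wif1, a secreted WNT inhibitor, at -0.51 on replicate 1 and -0.21 on replicate 2, and the difference was not tested. Immediate early and heat shock genes had medians of 0.16 on replicate 1 and -0.13 on replicate 2, with Fos at 0.91 on replicate 1 and -0.36 on replicate 2, a difference that was not tested either.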

How the results depend on the processing

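The directions of the 24 named genes held in every setting in which they were measured. With each array alone this follows from how the genes were chosen, and the other settings rework the same 2 arrays. It is therefore not independent evidence for the directions. All 24 lost the call with median centring and with dim probes kept, 2 (Serpinb5 and Cxcl13) with the prior with trend and 5 with unpaired channels, and none in the others. With median centring and with dim probes kept the ratios stayed near those reported (Upk3a 1.57 and 1.55, Prm1 -2.19 and -2.21), and 76 and 74 genes were at least 1.5-fold apart in one direction. Nkx6-3 read -2.57 with processed signals and -2.50 with the deposited values, and Serpinb5 1.82 and 1.83. Of other genes named in the text, Upk2, Gpm6a, Nkain4, Lrrn4, Wt1 and Rn18s were not followed over the settings. Among genes followed that had not passed, those that gained the call were Scnn1a in 7 settings, Lama3 in 5, Ivl in 4, Foxf1 in 3 and Id1 and Hhip in 1 each. The cause was not tested. Genes that passed numbered 194 with Agilent's processed signals (131 higher in labelled knockout, 63 in labelled control), 115 without background correction (82 and 33), 131 with an offset of 0 (93 and 38), 191 with the authors' deposited values (126 and 65), 197 with the prior with trend (132 and 65), 0 (0 and 0) with median centring and 0 with dim probes kept, against 66. The fit with no replicate block, the 4 channels unpaired, gave 29 (17 and 12), all 29 among the 66. At least 1.5-fold on each array were 154 genes with processed signals (107 and 47) and 145 with the authors' deposited values (101 and 44), and at 2-fold 18 (10 and 8). A single array gave 233 to 530 genes past 1.5-fold (126 to 185 in labelled knockout, 48 to 404 in labelled control). Genes at least 1.5-fold apart in opposite directions numbered 322 with median centring and 43 each with processed signals and the deposited values, against 23. The correlation of the arrays was -0.24 with median centring. Aquantile left every ratio as it was and tests nothing.

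Urothelial differentiation (mean 0.60) and general epithelium (0.19) no longer passed with an estimated correlation (adjusted p = 0.669 for both) or with fry (adjusted p = 0.554 for both), and the remaining 13 lists lost the call there too. With 2 arrays these tests have 1 residual degree of freedom, and 0 of 32 lists had an unadjusted p under 0.05 in either. A lost call there therefore cannot decide whether a list differs. The estimated correlation was -0.0105 for general epithelium and 0.0294 for urothelial differentiation, near the preset 0.01. For other lists that passed at the preset it was far above 0.01. It was 0.505 for hedgehog, 0.436 for endothelium, 0.35 for FGF, 0.345 for skeletal muscle and 0.275 for ureteric mesenchyme. With 1 residual degree of freedom these estimates are imprecise and cannot decide whether the preset holds. The urothelial mean was 0.55 to 0.68 with both arrays and 0.49 to 0.70 with single arrays. Basal epithelial genes passed with the mean over probes (0.13, adjusted p = 0.00551, range over settings 0.00551 to 0.809), and the sex check list with dim probes kept (0.12, adjusted p = 0.0415, range 0.0415 to 0.895). NOTCH, ureteric mesenchyme and endothelium did not pass with processed signals or the deposited values, nor ureteric mesenchyme and fibroblast matrix with median centring. Single arrays changed the sign of list means that had not passed: SMAD proteins -0.18 to 0.0282, TGF-beta-SMAD targets -0.18 to 0.0339, basal epithelial cells -0.0182 to 0.17, nephric duct -0.10 to 0.0667, canonical WNT targets -0.28 to 0.13, smooth muscle -0.11 to 0.16, red blood cells -0.0210 to 0.12, neurons and glia -0.42 to 0.60, nephron -0.0701 to 0.18, immediate early genes -0.22 to 0.23 and the sex check list -0.40 to 0.62. Without a change of sign, BMP-SMAD targets ran from 0.0334 to 0.14, p53 targets from 0.0227 to 0.12, gonad and adrenal from 0.00806 to 0.0477 and hypoxia from -0.0195 to -0.00547. Gonad and adrenal read -0.00763 with dim probes kept, and hypoxia 0.0157 with median centring and 0.00223 with the mean over probes. With single arrays these genes changed sign too: Pcp4 -0.39 to 0.89, Col1a2 -0.91 to 0.10, Fabp7 -0.0313 to 0.75, Th -0.0172 to 0.71, Prph -0.50 to 1.10, Tubb3 -0.72 to 1.08, Nefl -0.60 to 0.86 and Fos -0.36 to 0.91. No test with one array was possible, since it leaves no residual degrees of freedom. Signals near background limit what is seen: 12907 probes were left out as dim.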

Other observations

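The test of the dyes in the labels was chosen after the result was seen.

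The genes in this paragraph passed the test outside the fixed lists and were chosen after their values were seen, with n = 2 arrays and SD in log2 from 0.01 for Pamr1 to 0.30 for Lgals3. Higher in labelled knockout were Sfn, which encodes an epithelial adaptor protein, at 1.69-fold, Trim29 1.84-fold, Ly6d 1.69-fold, the WNT ligand gene Wnt10a 1.77-fold, the ceramide synthase gene Cers3 1.64-fold and the galectin gene Lgals3 1.73-fold. Fxyd3, a regulator of the sodium pump, was 2.01-fold higher and Rab27b, a GTPase of vesicle transport, 1.99-fold. In labelled control, Vsig1 was 1.69-fold higher, Pamr1 1.69-fold and Tinag, a basement membrane antigen gene, 1.78-fold. With the 4 channels as unpaired samples Fxyd3, Rab27b and Pamr1 still passed and the others in this paragraph did not, and with processed signals Ly6d read log2 1.39 and Vsig1 -1.45. They were not tested as a group.

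Prm1, at log2 -2.23 and -2.19, was 4.63-fold higher in labelled control. RNA of spermatids from the male embryos themselves as the source is argued against, since Prm1 did not follow sex. RNA of spermatids from elsewhere need not follow the sex of the embryos, so the sex labels cannot speak to it. Its signal in labelled control was 7870 on the array labelled female and 7286 on the male array. In that channel of the female array Ddx3y stood at 4.98% of the mean of the male array. In the test, 5 of 11 other spermatid genes were well above background in the labelled-control channels of both arrays, fewer than it required. Prm2 (0.00818 and 0.05) and Tnp1 (0.03 and 0.09), which spermatids make in abundance like Prm1, had ratios near 0. Tnp2, also above background in labelled control, read -0.60 and -0.19 in the direction of Prm1. In labelled knockout Tnp2 was not above background on replicate 2. The signals of these genes in labelled control were only 127 to 229, near background, so their ratios decide little about Prm1. Some transgenes carry a piece of Prm1 as a polyadenylation signal, and whether this Cre does is not given in the sources used here. If it did, Prm1 would mark the Cre-carrying sample, and the dyes of the genotypes may be exchanged in the labels of both arrays. That is also how the authors' deposited table would read by its titles. In the labelled-knockout channels the single Prm1 probe gave signals of 1680 and 1594, also well above background, so neither genotype lacked a signal there. Whether all of that signal came from Prm1 transcript was not tested. Whether Cre is the source of Prm1 was not tested either. Smad4, at -0.33 ± 0.36 (SD, n = 2, moderated standard error 0.14), leaned the way the labels give (limma unadjusted p = 0.0416). Both probes lay below 0 on both arrays, at -0.58 and -0.08 and at -0.09 and -0.33. Smad4 does not decide whether the dyes are exchanged, because it did not pass after adjustment and its probes may lie outside the floxed part. SMAD target genes do not decide it either. Msx2 (log2 0.96, limma adjusted p = 0.0359) and Id1 (0.53) were higher in labelled knockout. Of 18 BMP-SMAD targets, 6 were above 0 and 3 below 0 on both arrays. Of 15 TGF-beta-SMAD targets, 3 were above 0 and 5 below 0, and neither list passed.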
